A study of Homo sapiens with 2 samples.

How the data were processed

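The series holds 2 single-cell RNA libraries, 1 per group, from H9-derived fibroblasts reprogrammed with MGT and miR-133 and given an empty vector or TBX20. Libraries were made with the 10x Genomics 3' chemistry after a cell sort, per the labels' protocols; the gate of the sort is not given in the sources used here. The deposited values are raw UMI counts per gene and barcode, written by Cell Ranger 6.1.1 per the file headers. The submitters' processing notes name Cell Ranger, Seurat 4.0.5, R 4.1 and the genome build hg19. Each table has 19937 features, of which 3 are vector sequences that the authors added and named MGTPURO, TBX20V1 and MGT133. In both tables every barcode has at least 500 UMIs. Whether the authors removed cells or doublets before deposit is not given in the sources used here. The reference at hand was of another build, so no coordinates are printed, and gene span lengths were taken from GENCODE by gene identifier for a single test.

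Barcodes were kept with at least 500 detected genes and at most 20% of UMIs from the mitochondrial genome. In the empty vector library 1148 of 6193 barcodes had fewer genes and 2129 more were above the mitochondrial limit, leaving 2916; in the TBX20 library these numbers were 1871 of 6617, 1861 and 2885. Median mitochondrial shares of kept cells were 8.12% and 5.94%. Counts were summed over kept cells per library and scaled to CPM, and the log2 ratio of TBX20 over empty vector was computed with a pseudocount of 1 CPM, which understates ratios of low genes. Folds in the text are ratios of CPM without pseudocount. Their intervals are exact conditional (Clopper-Pearson) intervals, those of shares exact binomial intervals and those of single levels exact Poisson intervals, at 95%, and all cover counting error only. Reads of overlapping genes and near-identical paralogs cannot be separated in these counts. With 1 library per group no test, p-value or standard error was computed.

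For each of 34 gene lists, 22 of functions and 12 of cell type markers, members with a mean of at least 5 CPM were measured. A member counted as higher or lower at 1.25-fold, and the list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean CPM in 20 bins. A percentile at or under 2.5 or at or over 97.5 was read as standing apart, as a description of these libraries. Tested on simulated counts for this comparison, with 10057 genes in the step, 100% of genes made 3-fold different were found at 2-fold or beyond in the right direction, 0% of genes made 1.5-fold different were, and 6 of 100 unchanged lists stood apart. Both simulated libraries came from a shared profile with counting error only, without spread between cultures or genes that vary together. The simulation therefore checks the calculation and not how often real unchanged genes or lists would stand apart.

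The genes named were set by rule before the data were examined, as were the lists, the filters, the thinning and most of the alternatives tried. The rule took the reprogramming factors, 25 anchor genes (1 more had been set and is not reported), the 12 highest and 12 lowest log2 ratios among genes with at least 20 CPM in one library (without the mitochondrial genome and clone-based names), and the 2 highest and 2 lowest measured members of each list. Factor levels were to be read from TBX20, MEF2C, GATA4 and TBX5; the vector rows and MEF2C were used instead. Vector rows were left out of the ranking and of the clustering.

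To compare detection per cell, each kept cell with at least 5000 UMIs was thinned to 5000 UMIs, leaving out 758 cells of the empty vector library and 1300 of the TBX20 library. Kept cells were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes without mitochondrial and vector rows, 30 principal components, 20 neighbours and a resolution of 0.5; the calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0. A cluster was described by its 10 leading genes by fold, and named only from the marker lists. Scrublet called 0 doublets in both libraries, so the caller had not worked and doublets were kept; leaving out the 5% of cells with the highest scores per library was tried instead.

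The alternatives were other scalings (median-of-ratios size factors, totals without the 50 most abundant genes), other cell filters (all deposited barcodes, at most 10% mitochondrial UMIs), equal weight per cell, a pseudocount of 0.1, minimum mean CPM of 1 and 20, thinned counts, thinning to 3000 or 8000 UMIs or none, and cluster resolutions of 0.3 and 1.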

Results

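The series asked what TBX20, a T-box transcription factor of the heart, adds to the direct reprogramming of human fibroblasts into cardiomyocyte-like cells. The cells were fibroblasts derived from H9, an established human embryonic stem cell line. They received MGT, a retroviral construct carrying MEF2C, GATA4 and TBX5, together with a miR-133 construct and either an empty vector or a TBX20 vector. Single cells were sorted and captured on the 10x Genomics platform, and 3' ends of transcripts were counted as unique molecular identifiers (UMIs). There was 1 library per group, so the differences have no replicate check. The empty vector library held 6193 barcodes and 70477936 UMIs, and the TBX20 library 6617 barcodes and 61845817 UMIs. After filtering, 2916 cells of the empty vector library remained, with a median of 15750.5 UMIs and 4215.5 detected genes per cell, and 2885 cells of the TBX20 library, with medians of 11897 UMIs and 3722 genes. The kept cells gave 43211873 UMIs in the empty vector library and 38518698 in the TBX20 library. Depth per cell was uneven, with 758 kept cells of the empty vector library and 1300 of the TBX20 library under 5000 UMIs. Intervals are 95% intervals that cover counting error only.

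The vector transcripts checked the labels. The TBX20 vector row, TBX20V1, had 8512 UMIs in the kept cells of the TBX20 library, or 221 counts per 1000000 (CPM), and 1 UMI in the empty vector library, a ratio of 9549 (1713 to 377214). After each cell was thinned to 5000 UMIs, 53.7% of cells of the TBX20 library held a TBX20V1 UMI (51.2% to 56.2%); unthinned, the share was 88.2% of the same cells and 62.9% of all kept cells, which include the shallower ones. The other vector rows, MGT133 and MGTPURO, were close between the libraries; the sources used here do not state which construct each row stands for. MGT133 stood at 135.6 CPM in the empty vector library and 150.9 CPM in the TBX20 library, and MGTPURO at 86.2 and 84.8 CPM. The MEF2C row may hold endogenous transcripts, vector transcripts or both, which these counts cannot separate. It had 1007 and 966 CPM, and its ratio lay on either side of 1 depending on how cells were filtered and weighted. The endogenous genes TBX20, GATA4 and TBX5 were not analysed here.

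In the TBX20 library the myosin heavy chain genes MYH6 and MYH7, cardiac myosin-binding protein C (MYBPC3) and a set of skeletal muscle genes were higher than in the empty vector library, and the regulators of calcium uptake PLN and SLN, the natriuretic peptides NPPA and NPPB and the gap junction gene GJA1 were lower. MYBPC3 was 22.5-fold higher, from 8.49 to 190.9 CPM, and PLN 6.68-fold lower (6.55 to 6.81). Nuclear genes of oxidative phosphorylation stood slightly higher as a group. Troponin T (TNNT2) was 1.90-fold lower, while cardiac actin (ACTC1) was 1.40-fold higher, so cardiac genes did not share 1 direction. Of 10079 genes with a mean of at least 5 CPM, 354 were at least 2-fold higher in the TBX20 library, 275 were at least 2-fold lower, and 9450 lay between. These counts describe the 2 libraries and not the conditions.

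The leading genes with higher values in the TBX20 library were EMC10 (ENSG00000161671 in the files), the muscle enolase ENO3, the muscle carbonic anhydrase CA3, the peptidylarginine deiminase PADI2, osteopontin (SPP1), MYBPC3, SMIM5, the skeletal muscle ryanodine receptor RYR1, fast skeletal troponin T (TNNT3), muscle creatine kinase (CKM), the muscle-enriched nicotinamide riboside kinase NMRK2 and the folate receptor FOLR1. EMC10 had 4.42 CPM in the empty vector library and 356.9 CPM in the TBX20 library, an 80.7-fold ratio (70.0 to 93.6). Clusters 6 and 9, which have EMC10 and GOLGA8A among their leading genes, gave 71.5% of its UMIs in the TBX20 library. Their barcodes in that library were shallow, with a median of 1546 UMIs. Without those clusters its log2 ratio was 4.51 instead of 6.05. ENO3 was 60.6-fold higher (53.2 to 69.2), CA3 42.2-fold (37.5 to 47.7), PADI2 29.9-fold (26.0 to 34.5), RYR1 29.9-fold (22.7 to 40.3) and NMRK2 19.2-fold (16.2 to 22.9). SPP1 was 31.4-fold higher (25.7 to 38.7), SMIM5 26.1-fold (20.8 to 33.2) and FOLR1 20.5-fold (16.5 to 25.8). Of 2826 SPP1 UMIs in the TBX20 library, 2240 came from 147 cells of a fibroblast-like cluster described below.

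Among genes with lower values in the TBX20 library, the neuronal adhesion gene NTM led by log2 ratio, with 278.6 CPM in the empty vector library and 4.62 CPM in the TBX20 library, a 60.3-fold ratio (52.0 to 70.3). The lysosomal protease CTSV was 41.4-fold lower (36.9 to 46.7), STUM 35.5-fold (28.1 to 45.4), the purinergic receptor P2RY14 36.7-fold (27.5 to 49.9) and the muscle glycogen-targeting subunit PPP1R3A 40.6-fold (26.4 to 65.9). IGFN1 had 1062 UMIs in the empty vector library and 5 in the TBX20 library, a larger ratio of 189 (80.9 to 584). ANGPTL7 was 31.4-fold lower (23.0 to 44.2), the hedgehog-binding protein HHIP 11.7-fold (10.4 to 13.1), COL14A1 11.2-fold (10.1 to 12.3), the formin DIAPH3 10.5-fold (9.85 to 11.3), the potassium channel KCNK6 9.53-fold (9.15 to 9.94) and ZNF385B 13.2-fold (10.4 to 17.0).

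Of 31 measured sarcomere genes, 14 were higher in the TBX20 library and 8 lower, at the size set for list members. Their median log2 ratio was 0.28, at percentile 99.99 of random lists matched on expression. MYH6 was 2.42-fold higher (2.39 to 2.46), from 822 to 1993 CPM, and MYH7 1.70-fold higher (1.68 to 1.72), from 1198 to 2034 CPM; these neighbouring paralogs are near-identical in part, so the split of reads between them is uncertain. The essential light chain MYL4 was 2.09-fold higher (2.07 to 2.11). The ventricular light chain MYL2 had 3 UMIs in the empty vector library and 592 in the TBX20 library, a ratio of 221 (75.4 to 1077), and reached 15.4 CPM. TNNI3 was 1.24-fold higher and TNNC1 1.22-fold higher. On the other side, TNNT2 stood at 8643 CPM in the empty vector library and 4548 CPM in the TBX20 library, the atrial light chain MYL7 was 1.52-fold lower, the muscle LIM protein CSRP3 2.80-fold lower (2.75 to 2.84) and nebulette (NEBL) 3.01-fold lower (2.95 to 3.07). ACTN2, at 300.2 and 280.3 CPM, was higher in the TBX20 library when each cell was weighted equally, with a log2 ratio of 0.70. The cardiomyocyte marker list, which shares most of these genes, had 7 of 18 members higher and 7 lower, with a median of 0.27 (percentile 99.84).

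The calcium handling list also split. Of 15 measured genes, 7 were higher and 4 lower, with a median of 0.28 (percentile 99.67) and a mean of 0.02; with each cell weighted equally the median was 0.23 and no longer apart from random lists. The sarcoplasmic calcium buffer CASQ2 was 3.81-fold higher (3.34 to 4.36), S100A1 2.34-fold higher (2.05 to 2.66) and the cardiac ryanodine receptor RYR2, at 2.08 and 5.95 CPM and so under the minimum for measured members, 2.85-fold higher (2.23 to 3.68). The calcium pump and its 2 small regulators were lower. PLN, the pump's inhibitor, went from 2058 CPM in the empty vector library to 308.3 CPM in the TBX20 library, SLN was 6.73-fold lower (6.60 to 6.85) and the pump itself, ATP2A2, 1.80-fold lower (1.75 to 1.86). Among 12 ion channel and gap junction genes, 4 were higher and 3 lower (median 0.13, percentile 79.43). GJA1, which encodes connexin 43, was 5.27-fold lower (5.13 to 5.43) and KCNE4 31.7-fold lower (20.6 to 51.5), while KCNQ1 was 6.89-fold higher (5.59 to 8.56) and ATP1B1 3.07-fold higher (2.94 to 3.21).

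Atrial genes stood lower as a group. Of 8 measured members, 6 were lower and 2 higher, and the median was -0.63 (percentile 0.02); NPPA was 2.42-fold lower (2.40 to 2.43), from 8208 to 3399 CPM, and the 2 higher members were MYL4 and NR2F1. Of 6 ventricular genes, 3 were higher and 2 lower (median 0.26, percentile 92.20), with NPPB 4.46-fold lower (4.37 to 4.54). Cardiac transcription factors other than the reprogramming factors were lower more often than higher, 9 against 1 of 20, with a median of -0.18 (percentile 0.18). The Notch target HEY1 was 7.04-fold lower (6.12 to 8.12) and the progenitor gene ISL1 7.19-fold lower (5.73 to 9.14). NKX2-5 had 20.1 and 15.1 CPM, HAND2 120.4 and 104.1 CPM, and MEF2D 30.8 and 38.2 CPM.

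For energy metabolism, which the series title names, nuclear oxidative phosphorylation genes stood slightly higher, and most members of the lists lay between the limits. Of 77 nuclear oxidative phosphorylation genes, 13 were higher, 1 was lower and 63 lay between. Their median log2 ratio of 0.18 exceeded nearly every random list (percentile 100). SDHB was 1.42-fold higher (1.36 to 1.47) and SDHD 1.37-fold (1.32 to 1.42), while SDHA was 1.30-fold lower and NDUFA4 1.08-fold lower. Transcripts of the mitochondrial genome went the other way, with 3 of 13 lower, 1 higher and a median of -0.23 (percentile 0.40). MT-ND2 was 1.36-fold lower and MT-ND6 1.35-fold higher. This direction depended on the cells taken, since the median was 0.16 over all deposited barcodes and 0.20 (percentile 99.77) within a fibroblast-like cluster. The cell filter limits the summed share of mitochondrial genome UMIs to 20%. In kept cells the median share was 8.12% in the empty vector library and 5.94% in the TBX20 library. This list is therefore not independent of the filter and is no separate result on metabolism. Of 19 genes of fatty acid uptake and oxidation, 8 were higher and 2 lower (median 0.17, percentile 96.96). The electron carrier ETFB was 2.05-fold higher (1.97 to 2.13) and the fatty acid transporter CD36 1.70-fold higher (1.62 to 1.78), while the lipid droplet protein PLIN2 was 2.26-fold lower (2.16 to 2.36) and PPARA 1.51-fold lower. The citric acid cycle had 1 of 17 genes higher and 0 lower (median 0.13, percentile 91.06); SUCLG1 was 1.36-fold higher. In glycolysis 1 of 17 was higher and 2 lower (median -0.06, percentile 6.46), with ENO1 1.40-fold higher and the glucose transporter SLC2A1 1.85-fold lower. Mitochondrial biogenesis and dynamics had 2 of 13 higher and 0 lower (median 0.11, percentile 84.07). The coactivator PPARGC1A was 1.31-fold higher (1.22 to 1.41), the nucleotide carrier SLC25A4 was 1.57-fold higher, and CKMT2 had 2.64 and 3.45 CPM.

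**Figure D1:**
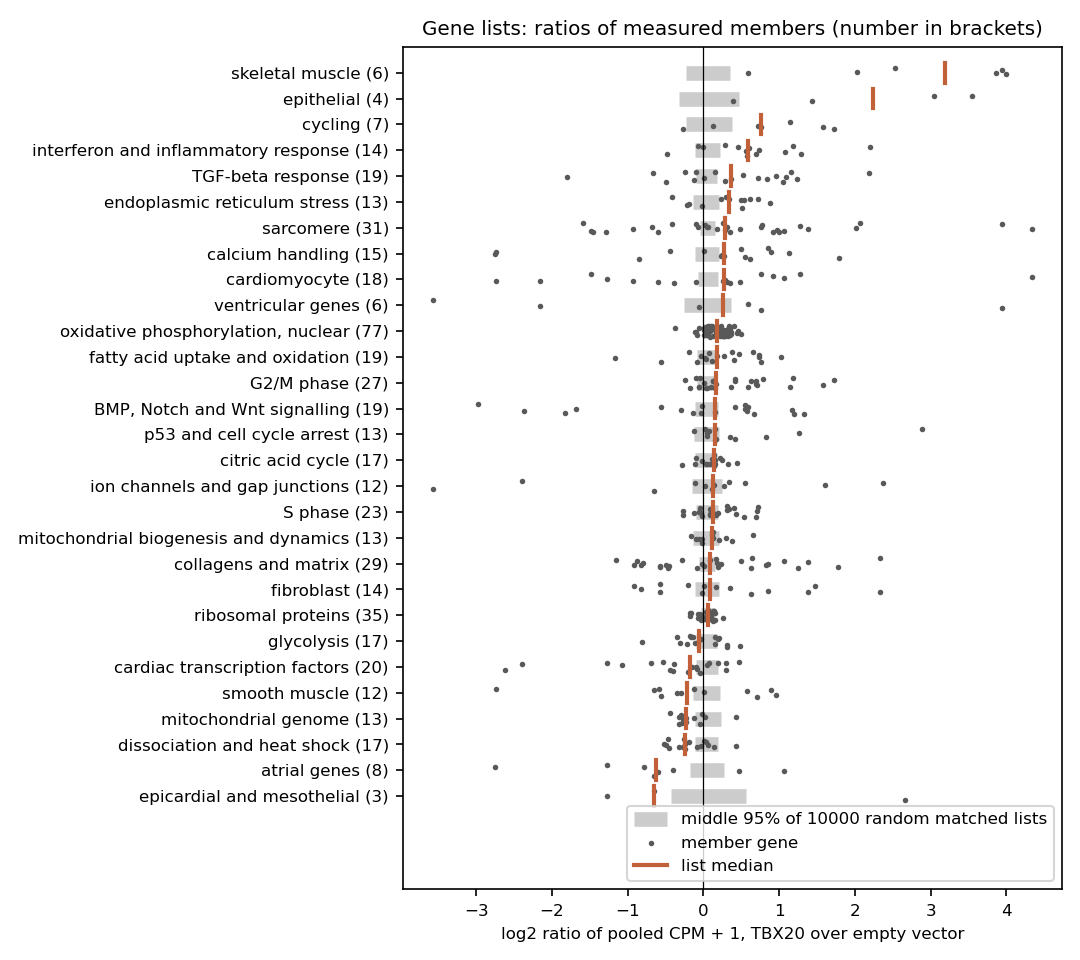
Log2 ratio of pooled CPM plus 1, TBX20 over empty vector, on the horizontal axis for each measured member (points) and the median (orange line) of 29 gene lists, with the middle 95% of medians of 10000 random lists matched on expression (grey). Skeletal muscle genes have the highest median, 3.19, and the atrial median lies at -0.63.

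The measured skeletal muscle markers were all higher, but only 6 of the 12 genes on that list passed the minimum. The 6 measured members had a median log2 ratio of 3.19 (percentile 100), with CKM 15.8-fold higher, from 33.7 to 531 CPM, TNNT3 16.9-fold (15.6 to 18.3), the myogenic factor MYF6 5.02-fold (4.17 to 6.08) and the acetylcholine receptor subunit CHRNA1 1.55-fold (1.37 to 1.76). The measured epithelial markers were also higher, 4 of 4 with a median of 2.23 (percentile 100), out of 10 genes on the list. Keratin KRT8 was 12.1-fold higher (11.3 to 12.9), the splicing regulator ESRP1 9.12-fold (8.15 to 10.2), KRT18 2.70-fold (2.65 to 2.75) and EPCAM 1.34-fold; under some alternatives 5 members passed the minimum, and the median was then lower, 1.39 with median-of-ratios size factors. The interferon and inflammatory list had 10 of 14 members higher and 1 lower (median 0.58, percentile 100), with IFI6 4.65-fold higher (4.46 to 4.85), IFIT3 at 22.1 and 55.3 CPM and the chemokine CXCL12 1.40-fold lower. Of 19 TGF-beta response genes, 10 were higher and 3 lower (median 0.36, percentile 100). TGFBI was 4.58-fold higher (4.40 to 4.78) and ID3 2.36-fold higher, against INHBA 3.50-fold lower (3.36 to 3.65) and TGFBR1 1.62-fold lower. Of 11590 TGFBI UMIs in the TBX20 library, 7788 came from 147 cells of the fibroblast-like cluster. Endoplasmic reticulum stress genes had 7 of 13 higher and 1 lower (median 0.34, percentile 99.83), led by XBP1 (1.86-fold) and HSP90B1 (1.64-fold), with TRIB3 1.35-fold lower and ASNS at 13.7 and 11.6 CPM. Of 17 dissociation and heat shock genes, 4 were lower, 1 was higher and 12 lay between (median -0.25, percentile 0.08), with FOS 1.47-fold lower, EGR1 1.43-fold lower and IER3 1.35-fold higher.

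Matrix and fibroblast genes went both ways. Of 29 collagen and matrix genes, 10 were higher and 10 lower (median 0.09, percentile 77.92), and of 14 fibroblast markers 6 were higher and 4 lower (median 0.08, percentile 68.76); both medians were slightly below 0 over all deposited barcodes. COL1A1 was 1.80-fold higher (1.77 to 1.83), decorin (DCN) 5.69-fold (4.99 to 6.51), LOXL2 3.47-fold (3.30 to 3.64) and PDGFRA 2.84-fold (2.64 to 3.06). Of 1354 DCN UMIs in the TBX20 library, 1212 came from 147 cells of the fibroblast-like cluster. COL3A1 had 882 and 871 CPM, POSTN was 1.79-fold lower (1.69 to 1.89), MMP2 1.92-fold lower (1.79 to 2.07) and FBN2 2.29-fold lower. Smooth muscle markers had 4 of 12 higher and 5 lower (median -0.21, percentile 0.51; -0.10 and no longer apart from random lists without the fibroblast-like cluster), with smooth muscle myosin MYH11 7.34-fold lower (6.55 to 8.24), CNN1 2.01-fold higher, RGS5 1.92-fold higher, ACTG2 1.60-fold lower and ACTA2 at 1292 and 1179 CPM. Of BMP, Notch and Wnt genes 9 of 19 were higher and 5 lower (median 0.16, percentile 94.81), with SFRP1 8.74-fold lower (7.75 to 9.89), BMP2 6.07-fold lower (5.18 to 7.13), ID2 2.68-fold higher and LEF1 2.71-fold higher. The cycling markers had 5 of 7 higher and 0 lower (median 0.75, percentile 99.87; 0.39 and no longer apart without the fibroblast-like cluster) at low levels, with TOP2A at 3.59 and 14.1 CPM and CENPF 3.16-fold higher; MKI67, under the minimum for measured members, had 1.60 and 7.11 CPM. TOP2A had a log2 ratio of 1.72, and 0.38 when cells were kept at no more than 10% mitochondrial UMIs. The S phase list (7 of 23 higher, 0 lower, median 0.12, percentile 86.95), the G2/M list (13 of 27 higher, 0 lower, median 0.16, percentile 97.06) and the p53 list (5 of 13 higher, 0 lower, median 0.16, percentile 93.61) lay within the range of random lists. In the p53 list the stress cytokine GDF15 was 8.15-fold higher (7.32 to 9.10) and CDKN1C 2.45-fold higher. Ribosomal proteins had 0 of 35 higher or lower (median 0.06, percentile 37.88). Of 3 epicardial and mesothelial genes, ITLN1 was 7.06-fold higher and TBX18 and ALDH1A2 were lower (median -0.65, percentile 0.87). The endothelial (2 genes), neural (1), chondrocyte and osteoblast (1), pluripotent (0) and immune (0) lists had too few measured members for a median.

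Across single cells thinned to 5000 UMIs, the 2158 cells of the empty vector library and the 1585 of the TBX20 library carried similar numbers of cardiomyocyte markers, a median of 13 of 20 in each and means of 12.3 and 12.4. Outside the fibroblast-like cluster the medians were 13 and 14 and the means 12.7 and 13, and within it the median was 5 in each. Detection of single genes differed. MYH6 was found in 47.0% of cells of the empty vector library (44.9% to 49.1%) and 78.6% of cells of the TBX20 library (76.5% to 80.6%), and MYH7 in 43.0% and 68.3%. PLN was found in 88.2% and 37.0%, GJA1 in 87.6% and 37.1%, NPPB in 51.8% and 23.3%, ATP2A2 in 71.3% and 52.1% and CKM in 8.0% and 48.8%. Unthinned, the same cells held MYH6 in 61.6% and 91.7%, PLN in 96.0% and 56.4% and CKM in 17.0% and 70.2%. TNNT2 was found in nearly all cells, 98.6% and 95.3%. The abundant genes were also found in a fibroblast-like cluster. At the same depth its cells held a TNNT2 UMI in 77.0% and 59.9% of cells and an MYL7 UMI in 89.3% and 85.7%. The same cells held MYH6 in 6.6% and 29.9%, MYH7 in 10.7% and 25.9%, PLN in 28.7% and 5.4% and GJA1 in 62.3% and 21.1%. They held ATP2A2 in 38.5% and 31.3%, NPPB in 19.7% and 5.4% and CKM in 0 of 122 and 15.6%. These shares may join free RNA and the cluster's own transcripts, so they are no plain background. In the empty vector library its GJA1 level was 324.5 CPM against 818.7 CPM in the other cells. Its MYH6 level was 13.3 against 882.2 CPM, a much smaller fraction.

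**Figure D2:**
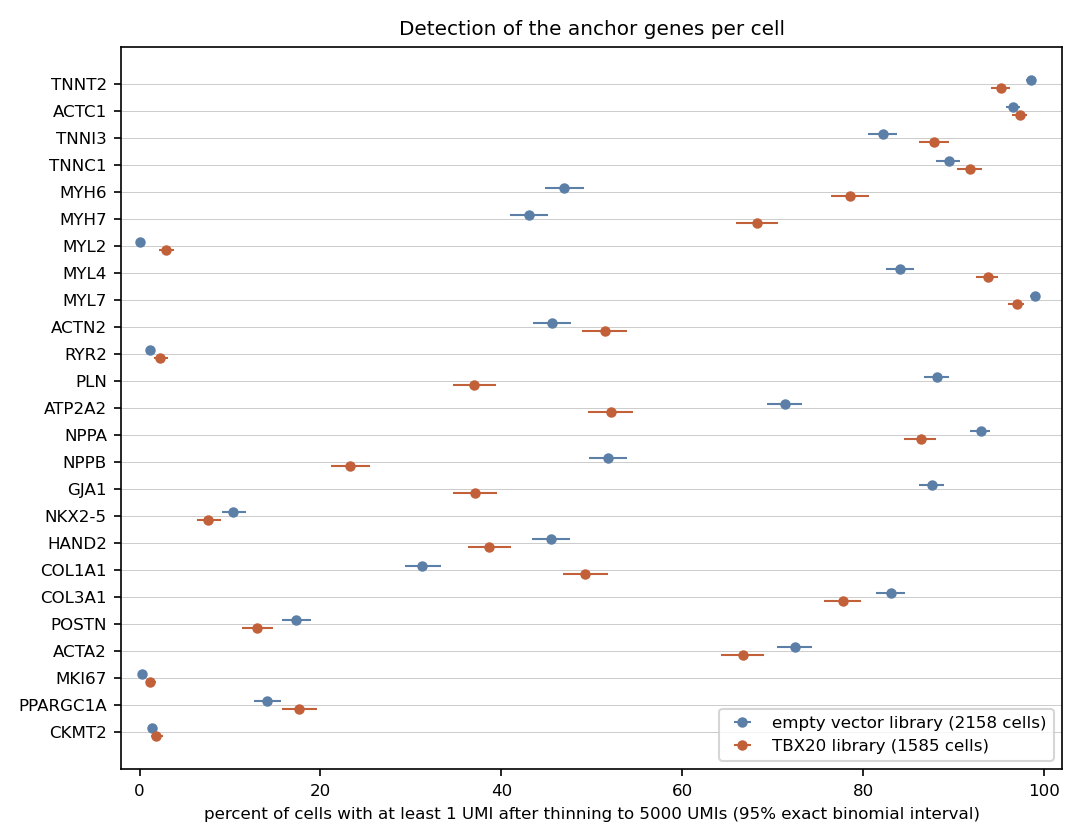
Percent of cells with at least 1 UMI of each of 25 anchor genes after thinning to 5000 UMIs, for the empty vector library (blue, 2158 cells) and the TBX20 library (orange, 1585 cells), with 95% exact binomial intervals. MYH6 and MYH7 lie farther right in the TBX20 library, and PLN, NPPB, GJA1 and ATP2A2 farther left.

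Outside the fibroblast-like cluster, 41.2% of cells of the empty vector library had no UMI of MYH6 or MYH7 (39.0% to 43.3%), against 10.9% in the TBX20 library (9.35% to 12.6%). At least 20 UMIs of the 2 genes were present in 21.4% of cells of the empty vector library and 48.2% of the TBX20 library. The median cell had 1 and 18 such UMIs. At this depth no PLN UMI was seen in 8.25% of these cells in the empty vector library and in 59.7% in the TBX20 library, which does not show that a cell lacks PLN, and the same holds for MYH6 and MYH7.

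**Figure D3:**
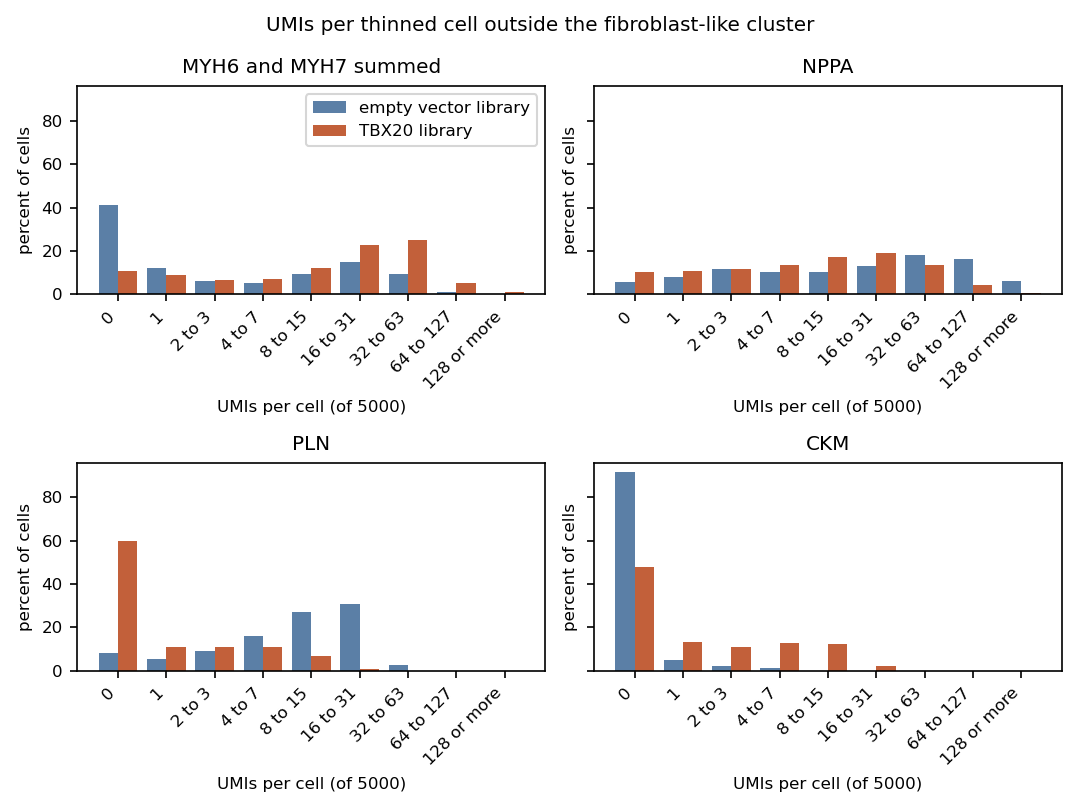
Percent of cells by the number of UMIs of MYH6 and MYH7 summed, NPPA, PLN and CKM, in cells thinned to 5000 UMIs outside the fibroblast-like cluster (empty vector library blue, TBX20 library orange). Cells with no MYH6 or MYH7 UMI make up 41.2% of the empty vector library and 10.9% of the TBX20 library.

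Joint clustering gave 9 clusters, and 5 of them, with 4778 cells, held over 90% of their cells from 1 library, so most clusters may mark a library and not a cell type. Cluster 7 was called fibroblast-like because it had the most fibroblast list genes among its 10 leading genes, though this was only 1 gene. Its 10 leading genes were BGN, DCN, SPP1, PLAU, TGFBI, COLEC10, IGFBP3, IL7R, DKK1 and ACTG2, of which 1 is on the fibroblast list and 1 on the smooth muscle list. Cardiac genes, among them NPPA and NPPB, led cluster 2, which held almost only cells of the empty vector library, and the clusters other than cluster 7 are given by number. Cluster 7 held 4.39% of kept cells of the empty vector library (3.67% to 5.20%) and 5.27% of the TBX20 library (4.48% to 6.15%); the sizes are not compared, because leading genes such as DCN and SPP1 differ between the libraries. Its COL1A1 level was 4353 CPM in the empty vector library and 4562 CPM in the TBX20 library, against 186.8 and 445.6 CPM in the other cells with at least 5000 UMIs. Its TNNT2 level was 481 and 218 CPM against 9188 and 4965 CPM, and its MEF2C level 249.4 and 199.0 CPM against 1040 and 1004 CPM. TBX20V1 was present in this cluster of the TBX20 library at 180.0 CPM, against 212.6 CPM in the other cells. Within the cluster, matrix genes were lower in the TBX20 library, with 13 of 29 lower and 8 higher (median -0.23, percentile 0.01), and G2/M genes were higher, 30 of 52 with 0 lower (median 0.40, percentile 100). Among its thinned cells, TOP2A was found in 6.56% in the empty vector library and 7.48% in the TBX20 library, and MKI67 in 4.92% and 7.48%. The G2/M ratios may therefore rest on few cells. Against their direction over all kept cells, the TGF-beta response list had 8 of 19 lower and 4 higher in this cluster (median -0.21, percentile 0.16), the endoplasmic reticulum stress list 4 of 13 lower and 0 higher (median -0.27, percentile 0.21), and the interferon and inflammatory list 4 of 15 lower and 4 higher (median -0.18, percentile 2). Smooth muscle markers were lower as well, 7 of 11 with 1 higher (median -0.72, percentile 0). Of 16 fibroblast markers, 8 were lower and 5 higher (median -0.26, percentile 0.03). Ribosomal proteins were lower by less (median -0.15, percentile 0.12). Of 18 cardiomyocyte markers, 10 were higher and 6 lower (median 0.44, percentile 99.99). These ratios rest on 122 and 147 cells and were chosen after the data were seen, since no cluster held the 200 cells of each library planned as a minimum.

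The amount of vector transcript, or of MEF2C, per cell was set against cardiac genes within each library, outside the fibroblast-like cluster. MEF2C UMIs may be endogenous, so they are no plain measure of vector level. In the TBX20 library, cells with 0 TBX20V1 UMIs had a mean of 13.3 cardiomyocyte markers and cells with 4 or more a mean of 12. Mean NPPA UMIs were 20.1, 18.4, 12.1 and 7.86 in cells with 0, 1, 2 to 3 and 4 or more TBX20V1 UMIs, and mean PLN UMIs 2.20, 1.72, 1.36 and 0.79. NPPA was also lower with more MGT133 UMIs, from a mean of 19.4 UMIs in cells with 0 to 9.29 in cells with 4 or more in the TBX20 library, and from 41.4 to 25.2 in the empty vector library. PLN followed MGT133 downward in the TBX20 library, from 2.08 to 1.09 UMIs, but not in the empty vector library, with 11.5 and 13.4 UMIs, and with MGTPURO it was lower in both, from 12.2 at 0 to 8.10 in the 20 cells with 4 or more in the empty vector library and from 1.95 at 0 to 1.22 at 2 to 3 in the TBX20 library. For NPPA, mean UMIs with MGTPURO in the empty vector library went the other way, from 38 in cells with 0 to 47.9 in cells with 4 or more, and in the TBX20 library from 18.4 in cells with 0 to 12 in cells with 2 to 3. Mean MYH6 and MYH7 UMIs went with MEF2C, from 16.3 in cells with 0 MEF2C UMIs to 26.5 in cells with 4 or more in the TBX20 library, and from 7.85 to 10.7 in the empty vector library; with MGTPURO they went from 22.8 at 0 to 31.3 at 2 to 3 UMIs and from 10.1 at 0 to 11.3 at 2 to 3 and 19.2 at 4 or more. With MGT133 they went down in the TBX20 library, from 25.6 at 0 to 14.7 at 4 or more, and stayed at 10.2 and 10.3 in the empty vector library; with TBX20V1 they were 25.4 at 0 and 23.1 at 4 or more. Cells are not replicates, so these are values without a test. Cell quality was not separated from vector level here. From barcodes with at most 20% to those with over 40% mitochondrial UMIs, TBX20V1 rose from 228.6 to 748.4 CPM in the TBX20 library. NPPA fell there from 3689 to 1714 CPM, and from 9121 to 2809 CPM in the empty vector library. PLN was 331.3 and 288.2 CPM in the TBX20 library. These levels are scaled to UMIs outside the mitochondrial genome, and barcodes over 20% are not in the bins above.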

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

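The tests in this part were set before their values were seen, but after the pattern itself had been noticed in the data. Barcodes left out of the comparisons carried signal above the control library. Of 3732 left-out barcodes of the TBX20 library, 39.98% (38.4% to 41.6%) held a TBX20V1 UMI, against 0 of 3277 in the empty vector library, with an upper bound of 0.113%. The empty vector culture did not receive the TBX20 vector. This contrast therefore cannot tell transcripts of cells from free vector RNA in the droplets of the TBX20 library. In left-out barcodes of the TBX20 library with over 40% mitochondrial UMIs and at least 5000 UMIs, MYH6 stood at 9020 and MYH7 at 12201 CPM of UMIs outside the mitochondrial genome.

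Those levels compare with 2200 CPM for MYH6 and 2235 CPM for MYH7 in kept cells of the TBX20 library at the same minimum depth, and the empty vector library had the same pattern, with MYH7 at 1340 CPM in kept cells and 4066 CPM in the mitochondria-rich barcodes. Against cells with more of the whole contractile and respiratory programme, the median log2 ratio of nuclear oxidative phosphorylation genes, mitochondria-rich over kept, was -1.09 in the empty vector library and -1.40 in the TBX20 library. What stays open is that damaged cells may have lost cytoplasmic RNA and kept long or nuclear transcripts: across genes outside the sarcomere list the ratio correlated with gene span (Spearman's rho 0.416 and 0.438 across 10668 and 10823 genes, which are not independent replicates), and ribosomal protein genes had medians of -1.78 and -2.04. The libraries differed here as well, with MYH7 3.00-fold higher in the TBX20 library in these barcodes and 1.67-fold in kept cells, and PLN 5.69-fold lower and 6.87-fold lower. The design gives no group that would test a biological explanation of the mitochondria-rich barcodes.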

How the results depend on the processing

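Alternatives chosen after the data were seen were keeping only cells with at least 5000 UMIs, leaving out the fibroblast-like cluster, leaving out clusters 6 and 9, leaving out the highest Scrublet scores, not thinning the same cells, and using barcodes above 20% mitochondrial UMIs; the other alternatives, the filters and the gene lists were set before the data were examined. The planned removal of Scrublet doublets gave no value because none were called. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Against random lists, 350 list medians under the alternatives gave the same reading as before, 13 a stronger one, 10 a weaker one and 1 the reverse. Single genes were less stable. Their log2 ratios stayed the same in 1477 checks and moved in 434. Differences in the share of cells with a UMI stayed the same in 146 checks, moved in 52 and reversed in 2. The count of genes at least 2-fold higher was 568 at a minimum of 1 CPM and 159 at 20 CPM, and the count of lower genes 151 at 20 CPM, because fewer or more genes enter; the other counts lay from 330 to 471 and from 270 to 356. The mitochondrial genome median reversed, to 0.16, over all deposited barcodes, which take in those above the mitochondrial limit. With each cell weighted equally the calcium handling median was 0.23, no longer apart from random lists, and the fatty acid median 0.23, now apart, as it was in thinned cells (0.28) and in cells with at least 5000 UMIs (0.17). The glycolysis median was -0.14 at no more than 10% mitochondrial UMIs, also apart. With all kept cells and no thinning, the difference in cells with an MYL7 UMI reversed, to 0.068 percentage points; in the same cells unthinned it was -0.063, and that of HAND2 reversed, to 0.337. The cause was not tested in these cases. The nuclear oxidative phosphorylation median stayed above random lists under all 13 alternatives, from 0.07 to 0.21. Depth limits genes near 1 UMI per cell, and 1 library per group limits every comparison.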

Other observations

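Tests in this part chosen after the data were seen are the ratio of EMC10 to vector UMIs, the share of cells with any skeletal muscle marker, and the CKM share in fibroblast-like cells; the others were set before their values were seen. The empty vector library fell mostly into 2 deep clusters that differed in myosin and in their leading genes. Cluster 2, with 1125 of its cells, had MYH7 at 2115 CPM, MYH6 at 1332 CPM and PLN at 1795 CPM, and cluster 4, with 859 cells, had MYH7 at 80.1 CPM, MYH6 at 218.9 CPM and PLN at 3087 CPM. TNNT2 was close between them, at 9618 and 9378 CPM, and MEF2C stood at 1105 and 878 CPM. The main deep cluster of the TBX20 library, cluster 1 with 1357 cells, had MYH7 at 2251 CPM, MYH6 at 2287 CPM and PLN at 336.5 CPM. These genes helped to form the clusters, so the values describe them and test nothing.

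A small cluster of 90 cells of the empty vector library and 47 of the TBX20 library was led by MMP1, GDF15, TRIB3, PSAT1, PHGDH, DDIT3, SLC7A11, FBXO2, SYBU and MTHFD2. In the TBX20 library, skeletal muscle UMIs per cell went with MEF2C, with a mean of 2.18 UMIs of CKM, TNNT3, TNNI2 and MYH3 in cells with 0 MEF2C UMIs and 4.84 in cells with 4 or more, outside the fibroblast-like cluster. In the empty vector library these means were 0.32 and 0.24.

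EMC10, a subunit of the endoplasmic reticulum membrane protein complex, had the highest log2 ratio of the genes ranked. Clusters 6 and 9 held 71.5% of its UMIs in the TBX20 library, in shallow barcodes with a median of 1546 UMIs. Without those clusters its log2 ratio was still 4.51, which argues against these clusters as the whole cause. Inside them its level was 90.7 CPM in the empty vector library and 9783 CPM in the TBX20 library. That is no separate support, because EMC10 is among the genes that lead these clusters. If vector reads were counted as EMC10, a shared source would keep 1 ratio of EMC10 to TBX20V1 UMIs. This ratio was 3.44 times higher in other cells than in fibroblast-like cells (2.89 to 4.14). Among thinned cells of the TBX20 library, EMC10 was found in 2.72% of 147 fibroblast-like cells and 25.4% of other cells. For TBX20V1 these shares were 47.6% and 54.3%. The ratio in fibroblast-like cells may therefore rest on few cells. The interval treats UMIs as independent and leaves out spread between cells, so it is too narrow. The values argue only weakly against vector reads. This ratio test replaced an earlier one that had left the question open. In the earlier test the share of cells with EMC10 was 1.78 times as high at 4 or more TBX20V1 UMIs as at 0. Where in EMC10 the reads end was not seen in these counts, so a vector integration, read-through from a neighbouring gene or nuclear RNA may be involved. A response of EMC10 to TBX20 or any other difference between the 2 cultures stays equally open, found and tested on the same 2 libraries.

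Skeletal muscle genes could come from a small separate population, from free RNA or from the TBX20 vector. Of 1438 cells of the TBX20 library outside the fibroblast-like cluster, 65.0% (62.4% to 67.4%) held any of CKM, TNNT3, TNNI2 and MYH3. A population of 20% with the fibroblast-like cells' 26.5% as background would give at most 41.2%. The values argue against a population of that size only. A larger separate population was not tested, and 47.8% of these thinned cells had no CKM UMI. The fibroblast-like cells also carry the vector and may hold such transcripts of their own. This test replaced an earlier one that had left the question open, in which 28.5% of the cells held 2 or more of the 4. Free RNA gives all cells a like share, and the CKM share in fibroblast-like cells was 0.30 times that in other cells. A dependence on the level of the vector transcript was not seen either, as cells with 4 or more TBX20V1 UMIs held 0.84 times the skeletal muscle UMIs of cells with 0. Thinned cells hold a mean of only 1.0 TBX20V1 UMI, so cells with 0 may carry the vector, and the added TBX20 itself stays open as the difference the design names, together with any other difference between the 2 cultures.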
